A study of Mus musculus with 6 samples.

How the data were processed

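The series holds 6 RNA-seq libraries of the mouse line ID8, 3 per Trp53 genotype, grown asynchronously without treatment. Per the labels' protocols, total RNA was isolated with a column kit, treated with DNase I and made into stranded total RNA libraries. Per the submitters' processing notes, STAR, featureCounts and edgeR were used with the build mm10. Their versions, order and settings and the gene annotation are not given in the sources used here.

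The authors deposited whole-number counts per gene symbol for 41327 genes, not normalized, with a column named for each library. The authors' deposited tables of repeats give a fold change on the log2 scale and an FDR, a p-value adjusted for multiple tests, for the single comparison of Trp53_KO with Trp53_WT, per repeat locus and read direction. The base of that scale is not stated by the authors and was checked on 709 rows in exons or 3' untranslated regions of genes with their own count-based fold change. The median ratio of the authors' deposited value to the gene's log2 fold change was 1.07 (quartiles 0.959 and 1.26), where natural logarithms would give 0.693 and log10 would give 0.301. The suffix of each row was read as the direction of its reads, because it matched the strand of the gene for 90.0% of 37148 rows in exons and 3' untranslated regions, against 53.2% for the strand of the repeat. Coordinates were taken as 1-based and closed, because 38617 adjacent loci began 1 base after the previous end and 1174 at it.

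Gene counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Of the 41327 genes, 18744 had no count in any library, and 13651 passed filterByExpr. Libraries were scaled by TMM, a quasi-likelihood model with the genotype as its only term was fitted to all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 and no fold threshold. The biological coefficient of variation was 9.75%. Standard errors of log2 fold changes were obtained as the absolute fold change divided by the square root of the F statistic. They are approximate, and for large changes with few counts in a group they can fall below counting error. CPM values are TMM-scaled. For genes with 0 counts in a group the fold was bounded with 3 counts over the group, and for 1 to 3 counts the ratio is given with an exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

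Replicates were compared before averaging. The chi-square per degree of freedom between the counts of replicate pairs was 2.01 for Trp53_WT replicates 2 and 3, 27.5 and 26.9 for Trp53_WT replicate 1 with replicates 2 and 3, and between 4.27 and 8.81 in Trp53_KO. No pair agreed within sampling noise, so all were kept as separate. On simulated counts for the same comparison and 13651 genes, the fit recovered 43 of 100 genes changed by 0.5 and 80 of 100 changed by 1 on the log2 scale, with 0 of wrong sign and 11 false calls. The simulation changed 200 genes, whereas 4130 were called in the data, so its recovery need not hold for the data.

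Before the data were examined, 22 gene lists were fixed, of which 17 had at least 5 tested members and were tested against other genes by camera with a preset correlation of 0.01, adjusted over the 17. Of these, 9 passed 0.05, and 3 passed with an estimated correlation. The genes named were fixed by a rule: Trp53, the 8 genes with the largest change in each direction that had an adjusted p under 0.05, a mean of at least 5 CPM, no overlap of the groups and a symbol that is not a predicted model (Gm with a number, Rik, or a clone name starting with AC, AL or BC), up to 4 members of each list with the lowest adjusted p, and Cdkn1a, Mdm2, Ifih1, Ddx58, Isg15, Cd274, H2-K1, B2m, Ifnb1 and Dnmt1. For repeats the rule took every class, the 8 subfamilies with at least 20 rows and the highest share of higher rows, and the 3 loci with the lowest FDR in each direction. Not every gene the rule took is printed.

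Repeat rows were counted at an FDR under 0.05, and the share of higher rows in each class or family with at least 50 rows, or subfamily with at least 20, was compared with all other rows by Fisher's exact test, two-sided, in scipy 1.17.1, adjusted by Benjamini-Hochberg over classes, over families or over subfamilies. Gene coordinates came from GENCODE M21 on GRCm38, the assembly of mm10, in which 11485 tested genes had a unique symbol. Repeats were called near a gene when they overlapped it or lay within 10 kb on either strand. All odds ratios and group tests on repeats were computed here from the rows of the authors' deposited table.

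Alternatives were other size factors (RLE, upper quartile), other filters, the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, stricter thresholds, an estimated correlation and fry for lists, and repeats outside annotated genes.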

Results

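Total RNA of ID8 cells, a line derived from C57BL/6 mouse ovarian surface epithelium, was sequenced from 6 untreated libraries, 3 labelled Trp53-/- (Trp53_KO) and 3 labelled Trp53+/+ (Trp53_WT). Trp53 encodes the tumour suppressor p53. Total gene counts were 19574772, 16597529 and 18686479 in Trp53_KO replicates 1 to 3 and 15319956, 19954170 and 18485982 in Trp53_WT replicates 1 to 3. The labels do not say whether the replicates came from separate cultures or clones, so p-values measure the spread between these libraries, which may be technical. Along the leading axis of a multidimensional scaling, which held 88.5% of the variance, the genotypes separated. The next axis set Trp53_WT replicate 1 at -0.84 against 0.37 and 0.45 for the other Trp53_WT libraries.

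The first question was whether Trp53 RNA followed the labels. Trp53 (chromosome 11, 69580359 to 69591873, GRCm38) was at 29.6, 25.5 and 25.3 CPM in Trp53_KO replicates 1 to 3 and at 110, 97.3 and 105 CPM in Trp53_WT. The means were 26.8 ± 2.4 and 104 ± 6.4 CPM (SD, n = 3 each), a log2 fold change of -1.95 ± 0.09 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.7e-07). Trp53 RNA was thus lower in every Trp53_KO library but remained detectable, and the labels do not state which part of the gene was altered.

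Genes of the p53 pathway fell in Trp53_KO. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), went from 41.0 ± 4.5 CPM in Trp53_WT to 1.59 ± 0.12 CPM in Trp53_KO (SD, n = 3 each). Its log2 fold change was -4.67 (edgeR, Benjamini-Hochberg adjusted p = 1.3e-08). Eda2r, a receptor of the TNF receptor superfamily, fell with a log2 fold change of -3.31 ± 0.09 (SE). Ephx1, microsomal epoxide hydrolase, fell with -1.94, Phlda3 with -1.86 and Mdm2, the ubiquitin ligase that targets p53, with -1.05. Of 33 tested p53 target genes, 26 fell and 3 rose at an adjusted p under 0.05 over all genes, and 27 fell and 3 rose when adjusted over the list alone. The list was lower than other genes (camera, Benjamini-Hochberg adjusted p = 3.3e-19), also with an estimated correlation (adjusted p = 0.032).

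Across the transcriptome, 1930 of 13651 tested genes were higher and 2200 were lower in Trp53_KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 30.3% of those tested. At least a 2-fold change was seen for 628 higher and 630 lower genes. The groups did not overlap for 46.0% of the tested genes, where chance gives 10% for 3 against 3. The count of calls ranged from 2977 to 4984 when 1 library was left out, the highest being without Trp53_WT replicate 1, and no gene called in both fits changed sign. The composition of the libraries differed with the genotype: Malat1, a nuclear RNA chosen after its values were seen, held 0.640%, 0.735% and 0.710% of the counts in Trp53_KO and 1.05%, 1.08% and 1.06% in Trp53_WT, and the 10 most abundant genes held 4.45% to 5.30% in Trp53_WT and a smaller share in each Trp53_KO library.

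Among the largest rises, Scrn1 had 830 counts in Trp53_KO and 0 in Trp53_WT, at least 270-fold higher against a floor of 3 counts over the group. Hs6st2, a heparan sulfate 6-O-sulfotransferase, had 3760 counts against 2, a ratio of 1836 with a 95% counting interval of 508 to 15164. Angptl7, an angiopoietin-like secreted protein, had 1061 counts against 3, a ratio of 345 with an interval of 118 to 1677. The forkhead factor Foxs1 reached 63.2 ± 2.6 CPM against 0.097 ± 0.044, and Lrrn4 reached 65.5 ± 0.81 CPM against 0.235 ± 0.094 (SD, n = 3). Ptprm, a receptor tyrosine phosphatase, Dclk1, a doublecortin-like kinase, and Tnc, the matrix protein tenascin C, rose by 7.14, 6.71 and 6.64 on the log2 scale. Their counts in Trp53_WT were 4, 11 and 25, so the size of these rises is uncertain.

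Among the largest falls, Grem1, a secreted antagonist of bone morphogenetic proteins, had 3561 counts in Trp53_WT and 0 in Trp53_KO, at least 1216-fold lower against the same floor. Col11a1, a fibrillar collagen chain, had 1037 counts against 1, a ratio of 1062 with an interval of 190 to 41987. Bnc1, the zinc finger protein basonuclin 1, went from 38.9 ± 1.9 to 0.073 ± 0.030 CPM, and the cationic amino acid transporter Slc7a2 from 145 ± 5.8 to 1.32 ± 0.23 CPM (SD, n = 3). Lad1, RP23-359F12.1, Als2cl and Gcnt3 had log2 fold changes of -7.79, -7.40, -5.88 and -5.46. The adjusted p-values of these 16 genes lay between 1.1e-09 and 4.4e-07 (edgeR, Benjamini-Hochberg).

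The title of the series names viral mimicry and immune evasion after p53 loss, so the next question was how interferon-stimulated genes behaved. None of 47 tested members rose, 30 fell and 17 did not pass the threshold, and 35 fell when adjusted over the list alone. Bst2, the antiviral protein tetherin, went from 30.4 to 8.60 CPM, a log2 fold change of -1.82 ± 0.09 (SE), and Lgals3bp, Parp14 and Ifi27 fell with log2 fold changes of -1.67, -1.06 and -0.91. Isg15, a ubiquitin-like modifier, was at 0.82 ± 0.29 against 1.91 ± 0.51 CPM (SD, n = 3; edgeR, Benjamini-Hochberg adjusted p = 0.016). That call did not hold without Trp53_KO replicate 2 or replicate 3 (adjusted p = 0.058 each, within a range of 9.1e-04 to 0.058 over the alternatives). The list was lower than other genes in camera (Benjamini-Hochberg adjusted p = 7.7e-08), a call lost with an estimated correlation (adjusted p = 0.17, the highest over the alternatives, of which the lowest was 5.1e-11). For p53 targets and each list below that is given with an estimated correlation, this was likewise the highest adjusted p of the alternatives, and the lowest lay between 5.0e-26 and 8.8e-04.

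**Figure D1:**
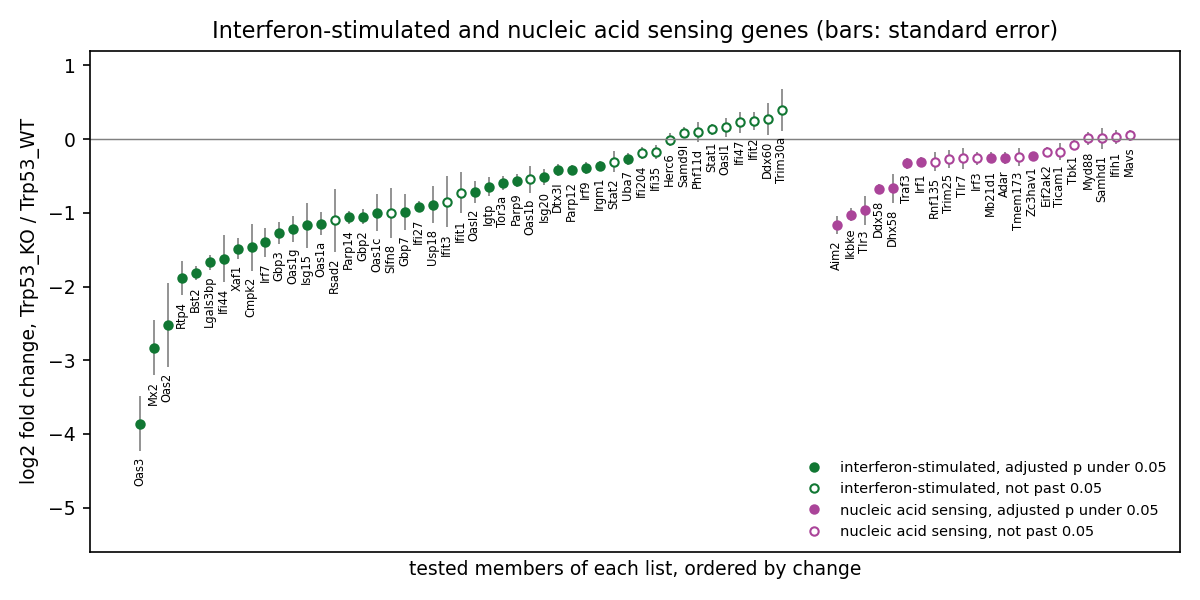
Log2 fold change of Trp53_KO over Trp53_WT (vertical axis) for the tested members of the interferon-stimulated and nucleic acid sensing lists, with 1 member of the latter not drawn, ordered by change, with standard errors as bars. Filled points passed an adjusted p of 0.05, and all 30 and 10 filled points of the lists lie below 0. The standard errors are approximate and can be too small for members with few counts.

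Nucleic acid sensing genes showed no rise either, with 11 of 23 tested members lower, or 12 when adjusted over the list alone. The cytosolic RNA sensor Ddx58, also called RIG-I, went from 73.7 ± 2.8 to 46.2 ± 1.4 CPM (SD, n = 3; log2 fold change -0.67 ± 0.07 SE), whereas Ifih1, the sensor MDA5, was at 31.0 ± 0.28 and 31.6 ± 3.6 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.87). Ikbke and Aim2 fell with log2 fold changes of -1.02 and -1.17. The list passed camera (Benjamini-Hochberg adjusted p = 0.0071) but not with an estimated correlation (adjusted p = 0.091). Of 21 interferon ligand genes in the table, 18 had 0 counts in all libraries, Ifnb1 among them, and the highest total over the 6 libraries was 12 counts.

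NF-kB targets and secreted immune factors were lower in part. Of 26 tested NF-kB targets, 13 fell and 1 rose, and 15 fell when adjusted over the list alone. Ptgs2, the prostaglandin synthase COX-2, went from 934 ± 74 to 234 ± 52 CPM (SD, n = 3), and Tnfaip2, Nfkbiz and Tnfaip3 fell with log2 fold changes of -1.10, -1.12 and -1.39 (camera, Benjamini-Hochberg adjusted p = 1.3e-04, and adjusted p = 0.091 with an estimated correlation). Of 24 tested chemokines and cytokines, 11 fell and 4 rose, or 13 and 7 when adjusted over the list alone. Ccl9 and Cxcl16 fell with log2 fold changes of -2.66 and -1.44, and Il34 and Ccl17 rose by 2.57 and 2.49 (camera, Benjamini-Hochberg adjusted p = 0.016, and adjusted p = 0.17 with an estimated correlation).

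Antigen presentation and checkpoint genes went both ways. Of 23 tested MHC class I genes, 8 fell and 3 rose, the same counts when adjusted over the list alone, and the list did not pass camera (Benjamini-Hochberg adjusted p = 0.25). The class I heavy chain H2-K1 rose from 24.6 ± 2.8 to 56.5 ± 5.3 CPM (SD, n = 3), a value that is uncertain because class I genes are close paralogs whose reads the counting could split. H2-T23, Tapbpl and the peptide transporter subunit Tap1 fell with log2 fold changes of -1.06, -0.89 and -0.80, and B2m, the class I light chain, was at 188 ± 6.2 against 201 ± 2.5 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.27). Cd274, which encodes PD-L1, went from 8.29 ± 0.99 to 3.93 ± 1.2 CPM (log2 fold change -1.06 ± 0.20 SE; edgeR, Benjamini-Hochberg adjusted p = 0.0033). Of 15 tested checkpoint genes 5 fell and 3 rose, or 6 and 3 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.52). Nt5e, the ecto-nucleotidase CD73, had 439 counts in Trp53_KO against 1, a ratio of 429 with a 95% counting interval of 76.5 to 16969. Lgals3, Raet1e and Ceacam1 fell with log2 fold changes of -1.06, -0.87 and -2.05.

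Genes of the ovarian surface epithelium and of the extracellular matrix rose as groups. Of 16 tested surface epithelium genes 10 rose and 4 fell, also when adjusted over the list alone. Upk3b, a uroplakin, went from 73.7 to 531 CPM, Amhr2, the receptor of anti-Müllerian hormone, from 0.48 to 39.2 CPM and Lrrn4 rose, while Bnc1 fell as given above (camera, Benjamini-Hochberg adjusted p = 2.9e-12, and adjusted p = 0.0499 with an estimated correlation). Of 25 tested mesenchymal and matrix genes 14 rose and 6 fell, or 15 and 6 when adjusted over the list alone. Col3a1, a fibrillar collagen, went from 3.08 to 268 CPM, Mmp2, a matrix metalloproteinase, from 1.48 to 8.70 CPM, and Twist2 had 331 counts against 0, at least 108-fold higher (camera, Benjamini-Hochberg adjusted p = 2.6e-09, and adjusted p = 0.0499 with an estimated correlation). Markers of other ovarian cell types rose in part. Of 5 tested granulosa and theca markers Inhbb, Star and Inha rose by 2.58, 3.04 and 1.28 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 8.5e-07, and adjusted p = 0.051 with an estimated correlation). The 3 tested fibroblast markers Dcn, Pdgfra and Col15a1 also rose, Dcn from 102 to 235 CPM. Of these Col15a1 lost its call without Trp53_KO replicate 1 or 2 or Trp53_WT replicate 2 or 3 (adjusted p between 0.068 and 0.097) or in DESeq2, within a range of 0.0097 to 0.097 over the alternatives.

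**Figure D2:**
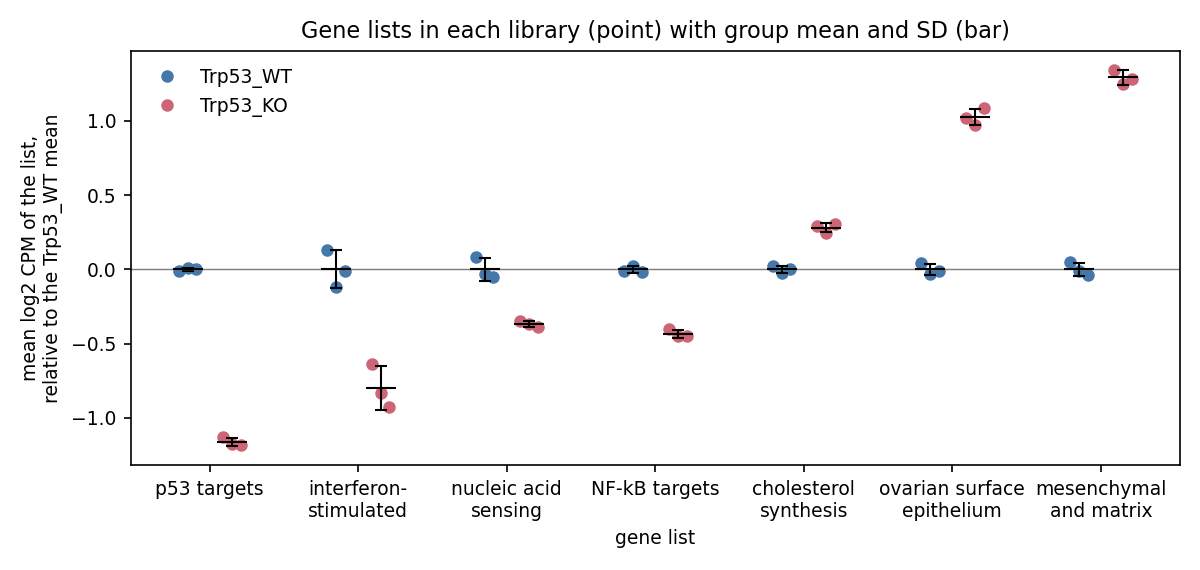
Mean log2 CPM of the tested members of 7 gene lists in each library, relative to the Trp53_WT mean (vertical axis), with points for libraries and bars for group mean and SD (n = 3 each). In each of the lists the Trp53_KO libraries lie on one side of all Trp53_WT libraries, with p53 targets between -1.13 and -1.19.

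Cholesterol synthesis genes rose, with 12 of 21 tested members higher and 0 lower, also when adjusted over the list alone. Hmgcs1 and Insig1 rose by 0.86 and 0.71 on the log2 scale, and Lss and Sc5d by 0.55 and 0.43 (camera, Benjamini-Hochberg adjusted p = 0.0094, and adjusted p = 0.091 with an estimated correlation). Cell cycle genes did not pass as a group, with a median log2 fold change of 0.003 and a mean of -0.03 over 44 tested members, of which 4 rose and 3 fell, or 3 and 3 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.89). Brca2 and Ccne1 fell with a log2 fold change of -0.67 each and Ccnb2 and Cdc20 rose with 0.39 each. Genes that silence repeats did not pass as a group either, with 8 of 35 higher and 3 lower, or 9 and 4 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.52). The methyltransferase gene Dnmt3a rose by 0.45, the histone methyltransferase gene Suv39h1 fell with a log2 fold change of -0.43, and Daxx rose by 0.43. Dnmt1, the maintenance DNA methyltransferase, was at 393 ± 23 against 342 ± 1.8 CPM (SD, n = 3; edgeR, Benjamini-Hochberg adjusted p = 0.037), a call lost without Trp53_KO replicate 1 or 3 or Trp53_WT replicate 2 or 3 (adjusted p between 0.082 and 0.13) or with the replicate number as a block (0.058), within a range of 0.014 to 0.13 over the alternatives.

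The remaining lists did not pass camera or had too few tested members. For DNA demethylation genes 3 of 10 rose and 2 fell (adjusted p = 0.46), for ATF4 stress genes 10 of 21 rose and 3 fell (adjusted p = 0.35), for glycolysis 1 of 19 rose and 8 fell (adjusted p = 0.27), and for epithelial genes 4 of 11 rose and 4 fell (adjusted p = 0.88; camera, Benjamini-Hochberg). Adjusted over the list alone, these counts were 3 and 2, 12 and 3, 1 and 9, and 4 and 4. The median and mean differed in sign for glycolysis (-0.06 and 0.13) and for epithelial genes (-0.08 and 0.35, with camera on the lower side). Named members included Gadd45a, which rose by 0.86, Hk2, at -0.63, and Krt14, at -2.53 on the log2 scale, all past the threshold. Of the ATF4 stress genes, Vldlr was at -2.38, and Nupr1, Chac1 and Trib3 rose by 0.86, 0.90 and 0.90, all called. The glycolysis gene Eno2 had 120 counts in Trp53_KO against 1, and the epithelial gene Grhl2 had 137 against 2, both called. MHC class II genes, germline genes, immune cell markers and endothelial markers had 3, 2, 2 and 4 tested members. Of these H2-DMb1, Tdrkh and Cd14 fell with log2 fold changes of -0.76, -1.31 and -2.47, Pecam1 and Esam rose with 3.64 and 1.13, and Flt1 and Egfl7 fell with -0.87 and -0.90. When adjusted over the list alone, 1, 1, 2 and 2 members of these lists fell and 0, 0, 0 and 2 rose. The call of Egfl7 was lost without Trp53_KO replicate 1 (adjusted p = 0.070) or Trp53_WT replicate 3 (0.071) or in DESeq2 (0.091), within a range of 0.016 to 0.091 over the alternatives. The germline gene Rhox5 had 25 counts in Trp53_KO against 51 and was not called (edgeR, Benjamini-Hochberg adjusted p = 0.26). Without Trp53_WT replicate 1 it passed, with a log2 fold change of -1.49 (edgeR, Benjamini-Hochberg adjusted p = 0.0026).

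The second comparison concerned repeat elements, for which the authors' deposited table gives a log2 fold change and a false discovery rate (FDR) per locus and read direction, with no values per library. Of 773731 rows in the authors' deposited table, 3002 were higher in Trp53_KO at an FDR under 0.05 (0.388%) and 2194 were lower (0.284%). The depth behind each row is unknown, and the libraries are those whose Malat1 shares differed by genotype. The authors' deposited table of higher repeats held 2853 rows, all of them the rows of the full table with an FDR under 0.05 and a log2 fold change above 1.

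Long terminal repeat elements, the remains of retroviruses, were over-represented among the higher rows. Of 127084 LTR rows in the authors' deposited table, 929 were higher (0.731%), an odds ratio of 2.29 against all other repeats (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 4.6e-85). Another 540 LTR rows were lower (0.425%), a share that was also above the 0.284% of all rows in the authors' deposited table. Lower rows were not tested by class. Copies of a repeat are not independent replicates, so these p-values describe the table, not the conditions. For SINE elements the authors' deposited table gave 1296 higher of 400949 (odds ratio 0.705) and for LINE elements 345 of 117122 (0.727), and their adjusted p-values by Fisher's exact test were 1.9e-20 and 5.4e-08. Outside annotated genes the SINE call was lost in the authors' deposited table (odds ratio 0.946, adjusted p = 0.72, within a range of 6.9e-34 to 0.72 over the alternatives), and the odds ratio of LINE elements was 0.297. DNA transposons (100 of 32089), simple repeats (185 of 55607) and low-complexity sequence (93 of 30313) did not pass in the authors' deposited table (adjusted p between 0.055 and 0.063), and satellites did, with 24 of 2963 higher (odds ratio 2.10, adjusted p = 0.0041). Outside annotated genes the odds ratio of satellites, computed from rows of the authors' deposited table, was 0.395. The direction thus turned and the call was lost (Fisher's exact test, adjusted p = 0.79, within a range of 0.0038 to 0.79 over the alternatives). For DNA transposons, simple repeats and low-complexity sequence the odds ratios outside genes, computed from the authors' deposited table, were 0.189, 0.313 and 0.352. All passed the threshold (Fisher's exact test, adjusted p = 5.9e-06, 5.8e-05 and 0.023, each the lowest over the alternatives, of which the highest were 0.10, 0.088 and 0.44). Among the other classes of the authors' deposited table, elements of unknown class had 13 of 1548 higher (adjusted p = 0.040), for which no alternatives were run, and ribosomal RNA repeats had 0 higher and 21 lower of 437. The classes Other, scRNA, tRNA, snRNA, RNA, LTR?, srpRNA, DNA? and RC held at most 5 higher rows each in the authors' deposited table.

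By family, the authors' deposited table showed the highest odds ratio past the threshold for ERV1, with 320 of 9227 rows higher (3.47%) and 132 lower (odds ratio 10.2, adjusted p = 1.1e-189). ERV1 was also over-represented among the lower rows of the authors' deposited table (odds ratio 5.37, adjusted p = 1.2e-48), which ERVK was not at the threshold (1.26, adjusted p = 0.060), and B2 was under-represented there (0.546, adjusted p = 5.8e-17). ERVK followed in the authors' deposited table with 373 of 37781 higher and 133 lower (odds ratio 2.78, adjusted p = 3.2e-58). Within the SINE class the B2 family stood apart in the authors' deposited table, with 744 of 115413 higher and 192 lower (odds ratio 1.89, adjusted p = 2.3e-44, Fisher's exact tests). Subfamilies of B2, chosen after their values were seen, differed in the authors' deposited table: B2_Mm1a had 373 of 12270 higher (odds ratio 9.05) and B2_Mm1t 191 of 11225 (4.68), whereas B3, B3A and B2_Mm2 had 61 of 42817 (0.353), 31 of 21333 (0.367) and 88 of 27768 (0.811). Of these all but B2_Mm2 (adjusted p = 0.57) passed the threshold by Fisher's exact test on rows of the authors' deposited table. L1, Alu and B4 elements had fewer higher than lower rows in the authors' deposited table, with 277 against 360, 214 against 282 and 182 against 196.

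**Figure D3:**
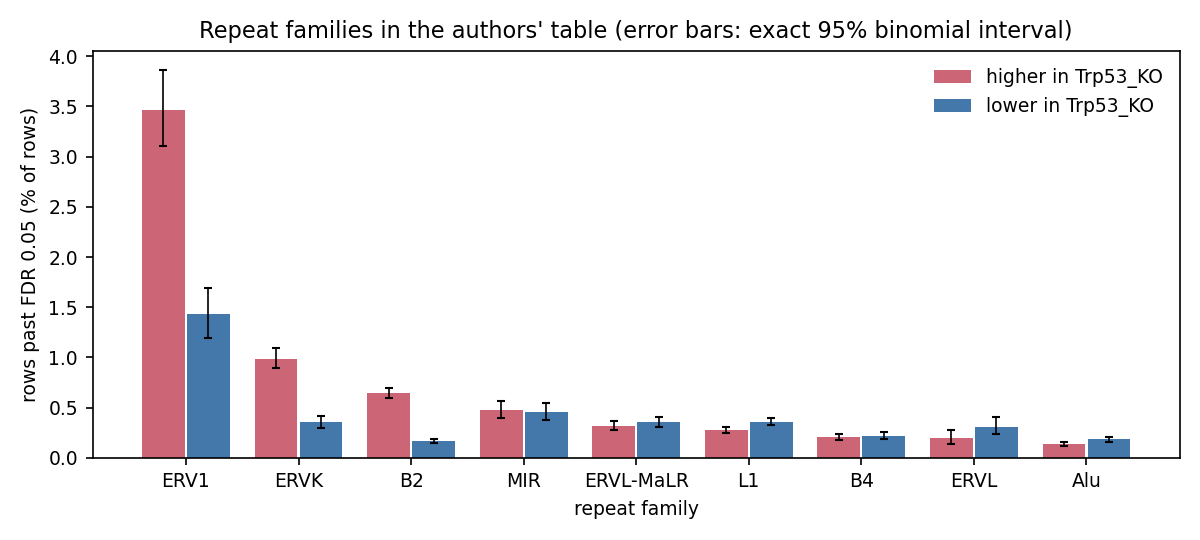
Percent of rows of 9 repeat families that were higher (red) or lower (blue) in Trp53_KO at an FDR under 0.05 in the authors' deposited table, with exact 95% binomial intervals as error bars, which cover counting error only. ERV1 has 3.47% higher and 1.43% lower rows, and Alu 0.139% and 0.183%.

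The subfamilies with the highest shares of higher rows were all endogenous retroviruses. Of 89 IAPEY4_I-int rows in the authors' deposited table, 35 were higher (39.3%), as were 84 of 263 RLTR6_Mm (31.9%), 152 of 501 MMVL30-int (30.3%) and 39 of 135 ERVB4_1B-I_MM-int (28.9%). ERVB4_1-I_MM-int, IAPLTR3-int, MMERVK10C-int and IAPLTR4 followed in the authors' deposited table with 5 of 29, 8 of 47, 131 of 906 and 3 of 23. For MMERVK10C-int 0 rows of the authors' deposited table were lower, which allows a share of up to 0.406% (exact 95% interval). Of the higher ERVB4_1B-I_MM-int rows in the authors' deposited table, 11 of 39 lay on chromosome Y. The 68 Y genes below 90 Mb in the gene table had 3 counts in all, and the line comes from ovary. Reads on such rows were thus likely assigned to the wrong copy, and the shares count rows, not transcribed copies.

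Reads of the higher rows of B2, ERV1 and ERVK mostly ran in the direction of the repeat, whereas the sense shares of L1, Alu, B4 and ERVL-MaLR lay between 34.0% and 50.5%. Of the higher B2 rows in the authors' deposited table, 92.5% were in the sense direction, against 51.2% of all B2 rows tested (exact 95% interval 90.3% to 94.3%; Fisher's exact test, adjusted p = 1.9e-132). The sense share in the authors' deposited table was 97.5% for higher ERV1 rows against 43.0% of those tested, and 80.7% for higher ERVK rows against 43.2%. Lower ERV1 rows of the authors' deposited table were mostly sense too (87.1%), whereas lower ERVK and B2 rows were not (47.4% and 45.8%). For higher L1 rows it was 44.0% against 38.1% in the authors' deposited table (adjusted p = 0.062), and for higher Alu, B4 and ERVL-MaLR rows it was 47.2%, 50.5% and 34.0% (adjusted p between 0.42 and 0.63).

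By the annotation in the authors' deposited table, 951 of 111909 intergenic rows were higher (0.850%, odds ratio 2.76), against 1406 of 590346 intronic rows (0.238%, odds ratio 0.272). In 3' untranslated regions of the authors' deposited table, 466 of 44248 were higher, in 5' untranslated regions 139 of 24524 and in other exons 40 of 2704, with odds ratios of 3.05, 1.49 and 3.89. Of all higher rows in the authors' deposited table, 51.4% lay in or within 10 kb of a gene that rose, against 14.6% of rows tested (odds ratio 6.26), and 3.33% near a gene that fell, against 17.2%. The corresponding share of higher rows near a gene that rose was 11.3% for ERV1, 22.3% for ERVK and 23.9% for B2, but 68.2% for L1 and 79.9% for Alu in the authors' deposited table. Of all rows tested in these families of the authors' deposited table, between 10.4% and 15.7% lay near such a gene.

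The loci with the lowest FDR were retroviral among the higher rows, and lay in 3' untranslated regions among the lower rows. The lowest FDR among higher rows of the authors' deposited table belonged to an intergenic IAPEY4_I-int on chromosome X, 74872947 to 74880004 (mm10), with a log2 fold change of 2.53 and an FDR listed as 0. Next in the authors' deposited table came an IAPEY4_I-int in an intron of Mrs2 on chromosome 13, 25007726 to 25015393, at 1.51 and an intergenic MMVL30-int on chromosome 14, 32117142 to 32119968, at 4.61. The lowest FDR among lower rows of the authors' deposited table was that of an L2c element in the 3' untranslated region of Cdkn1a on chromosome 17, 29100537 to 29100717, at -4.87. Its reads ran on the strand of Cdkn1a, whose own log2 fold change was -4.67, so the row can hold reads of that gene. Low-FDR lower rows in the 3' untranslated regions of Slc14a1 (chromosome 18, 78101108 to 78101150) and Nrn1 (chromosome 13, 36726437 to 36726475) were at -3.45 and -2.75 in the authors' deposited table. Such rows may likewise hold reads of their host genes.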

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

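Results without chromosome X and a block of chromosome 4, or without chromosome Y, were chosen after seeing the data, and the other alternatives were planned. The calls of genes were 1388 to 2418 higher and 1589 to 2566 lower when 1 library was left out, and no setting moved either count by over 1.5 times except the stricter thresholds, with 1199 higher and 1379 lower genes at an adjusted p under 0.01 and 628 and 630 at a log2 fold change of at least 1. The replicate numbers gave no sign of pairing: deviations of same-numbered libraries correlated at -0.05, 0.08 and -0.12. Trp53_KO replicates 1, 2 and 3 correlated best with Trp53_WT replicates 3, 2 and 1, and the reverse. With 3 libraries per group this cannot exclude a pairing. The fit with the replicate number as a block called 3806 genes. No called gene shared with any of the other gene fits changed sign. With an estimated correlation the adjusted p was 0.17 for interferon-stimulated genes and for chemokines, 0.091 for nucleic acid sensing, NF-kB targets and cholesterol synthesis and 0.051 for granulosa and theca markers. With fry, which does not compare a list with other genes, lists that had not passed had an adjusted p of 0.0045 (MHC class I), 0.0091 (DNA demethylation), 0.011 (ATF4 stress), 0.0016 (epithelial) and 0.023 (glycolysis). Neither H2-DMa (log2 fold change -0.29 to 0.22) nor Ifih1 (-0.039 to 0.114) kept its sign when 1 library was left out, and neither was called.

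Of the repeats in the authors' deposited table, 1767 were higher and 1350 lower at an FDR under 0.01, and 930 and 426 outside annotated genes, where fewer rows are tested. Outside genes the odds ratio among higher repeats was 0.189 for DNA transposons, 0.352 for low-complexity sequence, 0.313 for simple repeats, 0.946 for SINE elements (no longer past the threshold), and turned to 0.395 for satellites, whose call was lost, and 0.420 for MIR elements, which then passed. DNA transposons passed at an FDR under 0.01 (0.714) and at a log2 fold change of at least 1 (0.744), low-complexity sequence at that fold change (0.762), and without chromosome X and the chromosome 4 block low-complexity sequence (0.764) and simple repeats (0.827) did. The cause was not tested. Over all settings, 298 values of results that answer a comparison were labelled unchanged, 13 stronger, 7 weaker, 8 moved and 1 reversed. For single items, 1521 values were labelled unchanged, 1 stronger, 57 weaker and 4 reversed. For counts of genes or repeats, the label unchanged refers only to the size of the count. For gene lists past the threshold in neither fit, it does not show that the direction was kept. A filter on mean expression, other size factors, the block and left-out libraries were not run for repeats, because the table used here gives no values per library. Depth limits genes of a few counts, such as interferon-stimulated genes under 1 CPM.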

Other observations

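The tests of explanations and the test of symbol groups here were chosen after the results were seen, except the one that leaves out libraries for chromosome X. Genes and subfamilies in this part were likewise chosen after their values were seen. At the imprinted Peg3 locus on chromosome 7, Peg3 was at 521 ± 27 CPM in Trp53_KO and 8.56 ± 0.45 CPM in Trp53_WT (SD, n = 3; log2 fold change 5.93 ± 0.08 SE; edgeR, Benjamini-Hochberg adjusted p = 5.2e-10). Its neighbour Usp29 had 476 counts against 1, a ratio of 465 with a 95% counting interval of 83.0 to 18396. Igf2r, another imprinted gene, rose by 1.12 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 5.2e-06). Xist was at 222 ± 13 against 546 ± 274 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0054). Among 71 groups of at least 15 genes that share a symbol stem, 0 passed camera (Benjamini-Hochberg) and 5 had an unadjusted p under 0.05, the lowest adjusted p being 0.12 for collagens and for semaphorins.

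Not every retroviral subfamily rose. Of 202 MMERGLN-int rows in the authors' deposited table, 59 were lower and 1 was higher, and 25 of 183 MMERGLN_LTR rows were lower and 0 higher, all 59 and 25 of them in the sense direction. These are ERV1 elements, as are MMVL30-int and RLTR6_Mm, which rose. For IAPEz-int the authors' deposited table had 9 higher and 4 lower of 5527 rows.

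Higher ERV1, ERVK and B2 loci are weighed first. Of the 1437 higher rows in the authors' deposited table, 20.7% lay in or within 10 kb of a gene that rose, against 13.7% of rows tested (odds ratio 1.65, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 9.1e-13). Host genes may thus add to part of the higher rows, but the share argues against called genes with a known position as the source of most. Genes not called, not tested or without a position, and reads reaching past 10 kb, were not covered. The sense share of 90.5% against 48.9% of rows tested argues against genomic DNA or unstranded background. ID8 comes from ovary, so reads on chromosome Y below 90 Mb, where 68 genes had 3 counts in all, most likely belong elsewhere. On this chromosome 24 of these loci were called higher, 23 of them below 90 Mb (3 genes beyond it had 6962 counts). Reads shared between near-identical copies thus likely add called loci on chromosome Y, and may inflate the number of loci elsewhere. Whether the rise comes from the Trp53 genotype or from another difference between the lines was not tested.

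Lower interferon-stimulated genes are weighed next. The list stayed lower without each of the 6 libraries, with a highest camera adjusted p of 1.0e-06 (Benjamini-Hochberg), and 14 of 22 members with a mean of at least 10 CPM fell and 0 rose, which argues against 1 library or low counts as the cause. With every tested gene, 1 of 10 splits of the libraries, the real one, gave 4130 calls and the highest of the others 0 (edgeR). The other splits mix the genotypes within each group, which widens the spread there, and 10 splits are too few for a share under 0.05. They thus decide nothing, and they did not examine this list alone. The list's call is lost with an estimated correlation (adjusted p = 0.17), and a difference between the lines other than Trp53 stays open.

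A segment of chromosome X is weighed last. Of 149 genes below 80 Mb with a mean of at least 5 CPM, 111 fell and 4 rose, with a median log2 fold change of -0.46 (quartiles -0.68 and -0.31). Over 148 genes beyond 90 Mb the median was -0.11 (quartiles -0.28 and 0.08), and 37 fell and 21 rose. Of these genes beyond 90 Mb, 66.9% were lower at any p-value, against 50.1% on autosomes. The fall was thus larger below 80 Mb. Counts per gene do not separate the active from the inactive X, so they cannot decide on a change along the whole inactive X. Without each of the libraries the median of the genes below 80 Mb was at most -0.44. Fewer DNA copies of the segment in Trp53_KO is a candidate explanation that cannot be told apart from other causes. In the authors' deposited table repeats outside genes in the segment had a median of -0.31 (95% interval -0.39 to -0.18, which treats rows as independent). The median of repeats outside genes in the authors' deposited table was 0 beyond 90 Mb and 0 on autosomes. Those of the segment were thus lower than elsewhere. Their interval did not lie wholly below the bound set for fewer copies, and DNA was not analysed here.

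Other regions differed too, and were not weighed. On chromosome 4, between 122836242 and 123054949, Ppt1, Cap1, Mfsd2a and Trit1 fell with log2 fold changes of -2.73, -2.22, -1.74 and -2.24, and of 338 repeat rows there in the authors' deposited table, the 23 outside genes had a median of -2.08, with 4 past the threshold. This was 1 of 7 runs of at least 4 neighbouring genes called in the same direction with an absolute log2 fold change of at least 0.58. All of them fell, and shuffled gene orders gave at most 5 runs (1000 shuffles). Some runs held adjacent paralogs, with Tmem254a, Tmem254c and Tmem254b on chromosome 14 and Prl2c3 and Prl2c2 on chromosome 13. Another lay in the X segment. Shuffling separates such neighbours, so the number of runs does not by itself show regional change. By chromosome, the median was 0.18 on chromosome 4, where 246 genes rose and 67 fell, and -0.19 on chromosome 12, where 32 rose and 131 fell.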
